A study of Mus musculus with 8 samples.

How the data were processed

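RNA was sequenced from RN2 mouse leukaemia cells treated with DMSO, RVX-208, OTX-015 or BBC1115, with 2 libraries in each of 4 groups, 8 in all. Per the labels, the cells come from a C57BL/6J background, total RNA was taken with Qiazol, and libraries were made with a directional mRNA kit (NEXTflex Rapid Directional). The labels call the libraries of a group biological replicates. Doses, times of treatment and sequencing batches are not given in the sources used here.

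The authors deposited 1 table of RPKM, reads divided by transcript length and by library size, with 20484 gene symbols and 1 column for each library. The submitters' processing notes name STAR, Cufflinks and the mm10 assembly, without versions, roles or the gene annotation used. No further scaling between libraries is stated, and the RPKM totals of the libraries ran from 375973 to 467673. All 8 columns were used and 0 were left out.

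The table holds no reads, so depth was estimated. In a library the lowest values stem from genes with 1 read. For each gene with 1 annotated transcript of over 2500 exon nucleotides and an RPKM under 0.15, the library size at which 1 read gives that RPKM was computed, and the most frequent size was taken. This gave between 10700000 and 18100000 reads. These are approximate, and a count test on reads could not be run, because the RPKM of genes with several isoforms could not be turned into whole reads.

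Samples were grouped by the treatment in the labels before the data were examined, as were the tests, the gene lists, the rule for naming genes and the alternatives listed at the end, other than a pair added later. Genes with RPKM of at least 1 in at least 2 libraries were kept, 9975 in all. A linear model with a mean for each group was fitted to log2(RPKM + 1) of all 8 libraries with limma 3.58.1 in R 4.3.3, with the variance trend, 4 residual and 6.81 prior degrees of freedom. The 6 contrasts were each compound against DMSO and each compound against each other. Tests were two-sided, adjusted by the Benjamini-Hochberg method over the kept genes of a contrast, with a threshold of 0.05. Error is given as the SD of the RPKM of 2 libraries. A fold is the ratio of the group means of RPKM, while a log2 fold change comes from the model, whose pseudocount of 1 shrinks it for low values. Intervals of log2 fold changes are 95% intervals of the model. The replicate numbers were not used as pairs.

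The 32 gene lists were fixed in advance and 27 had the minimum of 5 kept members. They cover leukaemia oncogenes chosen for known sensitivity to BET inhibitors, genes induced or repressed by BET inhibitors, BET and P-TEFb genes, MLL and HOX targets, MYC targets of ribosome biogenesis, ribosomal proteins, DNA replication, mitosis, monocyte, neutrophil and stem cell genes, p53, interferon, NF-kB, immediate early, cholesterol, LXR, ATF4, unfolded protein, heat shock and NRF2 genes, glycolysis, oxidative phosphorylation, autophagy, histones, and mast, basophil and eosinophil markers. The 5 not tested are aryl hydrocarbon receptor targets and markers of T and NK cells, of B cells, of erythroid cells and megakaryocytes, and of fibroblasts and stroma. The p53 list also holds apoptosis genes. Some genes stand in several lists. Each list was tested with camera at a preset correlation of 0.01 against the other kept genes, adjusted over the lists of a contrast, and again with an estimated correlation, under which 0 lists passed in any contrast. The preset assumes that genes of a list vary nearly independently between libraries. A shift is the median log2 fold change of a list less that of all kept genes, and it is described, while camera is the test. Member counts are given over all genes and adjusted over the list alone.

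Named genes are a fixed panel of 17 genes, the 10 largest log2 fold changes in each direction against DMSO and the 5 largest between compounds, and up to 4 called members of each list with the largest change. The largest changes were taken among called genes with a mean of at least 5 RPKM in a group and both libraries beyond both of the other group. After the data were seen, the next genes by the same rule were added in place of genes listed at 0, for which no fold is given. The text names part of these genes, and a few of them are not reported here.

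Agreement between compounds was measured by r and covariance of log2 fold changes across genes and by the overlap of calls beside the number for independent calls. The compounds share the DMSO libraries, so the values were set beside 100 simulations of unchanged groups with shared controls. After the data were seen, 100 further sets were simulated with RVX-208 unchanged and the other responses kept. The size of response was the slope through the origin over genes called with 1 compound and not listed at 0. Coordinates and exon lengths came from GENCODE M21 on GRCm38, the mm10 assembly, in which 19934 symbols were matched.

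The methods were tested on simulated data, with each gene's mean over all 8 libraries and the spread fitted over all 4 groups. Changes were planted in OTX-015 against DMSO. In 20 sets of 9975 genes with 200 changed, 87.8% of 1.5-fold and 99.3% of 2-fold changes were recovered. Of the calls, 6.6% fell on unchanged genes. A shifted list was called in 20 sets and an unshifted list had p under 0.05 in 1. Genes were drawn independently, so the unshifted list does not test the preset correlation of camera. Far fewer genes were changed than in the data, where 64.3% of genes were called with OTX-015.

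Alternatives chosen in advance were pseudocounts of 0.1 and 0.5, no filter and a filter of 5 RPKM, quantile normalization, upper-quartile scaling, rescaling to a common total (TPM), only the 2 groups compared, no variance trend, robust variance, the replicate number as a block, each library left out in turn, an estimated correlation and fry for lists, and thresholds of 1 on the log2 scale and 0.1 on adjusted p. After the data were seen, a fit without genes listed at 0 and one with each library's length trend removed were added. Numbers of settings in which a list or gene passed, and ranges of its adjusted p, leave out fry and the estimated correlation. Groups of 2 libraries allow no test for a single deviating library and no count of other splits of the samples.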

Results

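RNA was sequenced from RN2 cells, a mouse acute myeloid leukaemia line engineered to carry the MLL-AF9 fusion and activated NRAS. Cells received the solvent DMSO or one of 3 compounds: RVX-208, OTX-015 or BBC1115. RVX-208 (apabetalone) is a BET inhibitor that favours the second bromodomain, OTX-015 (birabresib) is a BET inhibitor that binds both bromodomains, and BBC1115 is a code name. The series title places the work in a search of DNA-encoded libraries for compounds against the BET proteins, which read acetylated histones and help start transcription. Each of the 4 groups held 2 libraries, described as biological replicates, and the 8 libraries were compared as RPKM, reads divided by the length of the transcript and the size of the library. The labels give no dose and no time of treatment, so the compounds are set side by side and are not matched for dose.

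The deposited table held 20484 genes, of which between 9291 and 9648 reached 1 RPKM in a library. It gives no read counts. The depth behind each library was estimated from its smallest values, at 18100000 and 11900000 reads for the DMSO libraries. The estimates were 10700000 and 13200000 reads for RVX-208, 13200000 and 14700000 for OTX-015, and 12800000 and 15700000 for BBC1115. Across the 9975 genes kept for testing, the log2 values of the replicates of a group correlated at r = 0.991 in DMSO, 0.9945 in RVX-208, 0.9934 in OTX-015 and 0.9939 in BBC1115. These correlations run across genes, which are not independent replicates. The p-values of every comparison rest on a spread between replicate libraries that is pooled over all 4 groups, so they speak for these cultures only.

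The comparison of OTX-015 with DMSO asked what a known inhibitor of all BET bromodomains did in these cells. Myc, which encodes a transcription factor that drives cell growth and ribosome production, fell from 97.8 ± 2.72 RPKM in DMSO to 3.74 ± 0.00612 RPKM in OTX-015 (mean ± SD, n = 2 libraries in each group here and throughout), which is 26.1-fold lower (log2 fold change -4.38, adjusted p = 1.9e-10). Hexim1, which encodes an inhibitor of the elongation factor P-TEFb, rose 5.22-fold from 23.3 ± 0.86 to 122 ± 8.89 RPKM (adjusted p = 6.52e-09). Egr1, an immediate early transcription factor, rose 13.8-fold from 12.4 ± 0.368 to 171 ± 9.19 RPKM. Ccr2, a chemokine receptor of monocytes, fell 19.4-fold from 21.1 ± 0.173 to 1.09 ± 0.0907 RPKM. Brd2, itself a BET gene, rose from 67.8 ± 5.52 to 223 ± 13.7 RPKM, although its exons overlap H2-DMa on the opposite strand and the strand used in counting is not given in the sources used here. Brd3 did not pass (15.3 ± 1.92 and 14.8 ± 1.55 RPKM, adjusted p = 0.728).

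With OTX-015, Gfi1, a repressor needed for granulocyte development, fell 7.61-fold (47.1 ± 0.524 to 6.19 ± 0.333 RPKM) and Cdk6 fell 4.07-fold (76.7 ± 14.4 to 18.8 ± 1.08 RPKM). Kit fell 3.65-fold (24.1 ± 2.09 to 6.62 ± 0.608 RPKM) and Myb fell 2.96-fold (274 ± 1.72 to 92.7 ± 5.59 RPKM). Csf1r fell from 7.91 ± 0.659 to 0.904 ± 0.0187 RPKM, Itgam from 76 ± 9.21 to 42.2 ± 2.06 RPKM and Bcl2 from 12.8 ± 1.5 to 7.86 ± 0.2 RPKM. Hoxa9 and Meis1, which MLL fusions keep active, rose slightly, from 73.2 ± 5.67 to 94.5 ± 4.91 RPKM and from 10.5 ± 0.0786 to 16.1 ± 0.803 RPKM. Cdkn1a, an inhibitor of the cell cycle, rose 2.07-fold from 66.4 ± 0.388 to 138 ± 10.4 RPKM. Among the genes with the largest changes, Tob1 rose 10.2-fold (4.76 ± 0.356 to 48.5 ± 1.58 RPKM), Nabp1 6.88-fold (10.6 ± 0.461 to 72.7 ± 3.56 RPKM) and Kctd12 6.73-fold (14.5 ± 1.92 to 97.8 ± 5.66 RPKM). Cldn15, which encodes a tight junction protein, fell 31.2-fold (45.1 ± 3.1 to 1.44 ± 0.307 RPKM), Tfap4 fell 27-fold (11.7 ± 0.728 to 0.432 ± 0.0954 RPKM) and Gpr84 fell 15.2-fold (21.3 ± 1.76 to 1.41 ± 0.0143 RPKM). Kcnn4, a potassium channel, stood at 17.9 and 19.1 RPKM in the DMSO libraries and at 0.319 and 0.431 RPKM in the OTX-015 libraries.

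In the mm10 assembly Myc lies on chromosome 15 from 61985391 to 61990374, Hexim1 on chromosome 11 from 103116231 to 103119725, and Egr1 on chromosome 18 from 34859823 to 34864984. Ccr2 lies on chromosome 9 from 124101950 to 124113557, Gfi1 on chromosome 5 from 107716657 to 107726036, and Myb on chromosome 10 from 21124935 to 21160984. Insig1, which appears with BBC1115, lies on chromosome 5 from 28071363 to 28078662, and Chac1 on chromosome 2 from 119351229 to 119354381. The annotation gives each of these 8 as a protein-coding gene with no exon shared with another protein-coding gene. Overlap with other kinds of genes was not checked, and the exons that the authors counted are not known.

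**Figure D1:**
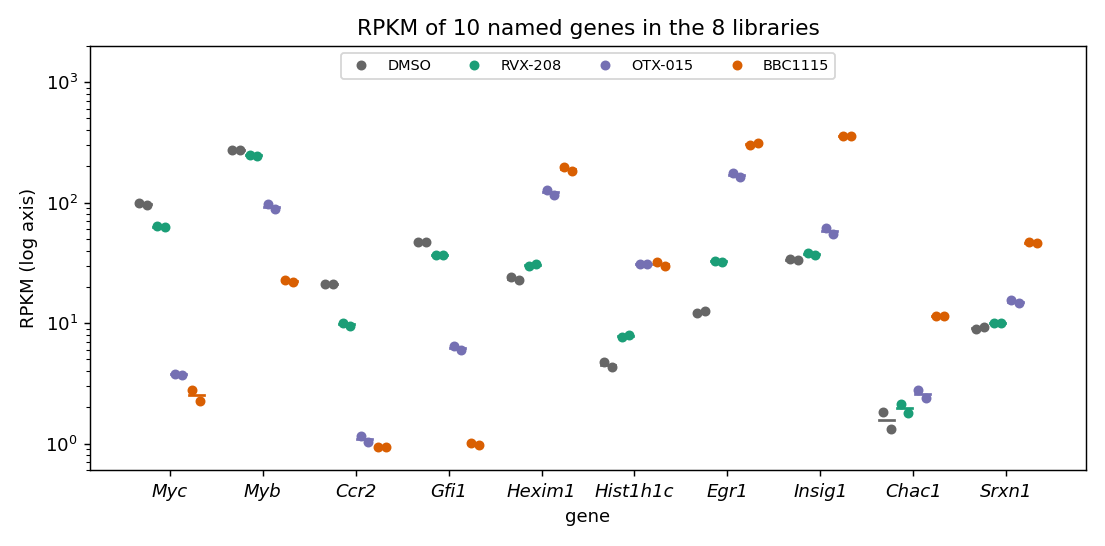
RPKM of 10 genes in each library on a log axis, with a point for each of the 2 libraries of a group and a bar at their mean. Myc averages 97.8 RPKM in DMSO, 63.2 with RVX-208, 3.74 with OTX-015 and 2.51 with BBC1115, while Insig1 averages 33.6, 37.4, 58.1 and 357 RPKM in the same order.

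At an adjusted p under 0.05, 2418 genes rose and 3992 fell with OTX-015, of which 368 and 970 changed by at least 1 on the log2 scale. The median log2 fold change of all genes was -0.134 with the RPKM as deposited and 0.035 after scaling each library to its upper quartile. The direction of small changes therefore depends on the scaling, with 3561 genes higher and 3066 lower after that scaling and 3641 and 3192 after quantile normalization. Shifts of gene lists are for this reason given relative to the median of all genes.

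MYC targets of ribosome biogenesis fell with OTX-015, in 60 of 61 genes (60 adjusted over the list alone), with a median shift of -1.18. Srm fell 9.19-fold from 122 ± 8.91 to 13.2 ± 1.9 RPKM, Dkc1 fell 6.53-fold from 74.9 ± 0.505 to 11.5 ± 0.382 RPKM and Gnl3 fell 6.13-fold from 89.5 ± 3.72 to 14.6 ± 1.12 RPKM. The list passed camera, which compares a list with the other genes (adjusted p = 6.85e-18, and adjusted p = 0.374 with an estimated correlation). DNA replication genes fell in 34 of 49 cases (34 adjusted over the list alone; adjusted p = 0.000307, and 0.593 with an estimated correlation). They included Tk1 (67 ± 2.84 to 24.4 ± 1.89 RPKM) and Ung (11.3 ± 0.316 to 2.98 ± 0.359 RPKM). Leukaemia oncogenes that were listed for known sensitivity to BET inhibitors fell in 12 of 15 cases (12 adjusted over the list alone), with a median shift of -1.42 (adjusted p = 0.000714, and 0.469 with an estimated correlation). Genes known to be repressed by BET inhibitors fell in 9 of 10 cases (9 adjusted over the list alone), with a median shift of -1.85 (adjusted p = 5.08e-05, and 0.374 with an estimated correlation).

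Markers of mature myeloid cells fell as groups with OTX-015. Monocyte and macrophage genes fell in 20 of 29 cases (20 adjusted over the list alone; adjusted p = 0.000742, and 0.469 with an estimated correlation). They included Cd14, a co-receptor for lipopolysaccharide (18.2 ± 0.0952 to 2.62 ± 0.621 RPKM), and Ms4a6c (26 ± 0.921 to 3.78 ± 0.39 RPKM). Neutrophil and granule genes fell in 18 of 20 cases (18 adjusted over the list alone; adjusted p = 0.000108, and 0.469 with an estimated correlation). They included Cebpe (83.1 ± 1.81 to 21.2 ± 3.73 RPKM) and Ms4a3 (344 ± 27.3 to 83.2 ± 8.07 RPKM). Mpo fell from 289 ± 3.8 to 214 ± 20.5 RPKM. Mast cell and basophil markers fell in 5 of 5 cases (5 adjusted over the list alone; adjusted p = 0.0111, and 0.374 with an estimated correlation), with Gata2 at 20.7 ± 0.738 RPKM in DMSO and 8 ± 0.607 RPKM with OTX-015. Stem and progenitor genes fell in 9 of 13 cases (9 adjusted over the list alone) but missed the threshold as a list (adjusted p = 0.099). They passed in 4 of 21 settings, under quantile normalization (0.0426), after upper-quartile scaling (0.0367), as TPM (0.0387) and with only the 2 groups compared (0.00888), over a range up to 0.272. Erg fell 6.26-fold from 12.6 ± 0.158 to 2.01 ± 0.421 RPKM and Cd93 fell 5.47-fold from 45.1 ± 7.65 to 8.24 ± 0.179 RPKM. Oxidative phosphorylation genes fell in 23 of 56 cases (22 adjusted over the list alone), a share near that of all genes, 3992 of 9975. Their own median was -0.252 as deposited, -0.025 under quantile normalization, -0.064 after upper-quartile scaling and -0.061 as TPM. The median shift was -0.12, and the list passed camera (adjusted p = 0.023, and 0.837 with an estimated correlation). That call held in 14 of 21 settings, with adjusted p from 0.000284 to 0.482, and it was lost without OTX-015 replicate 2 (0.056) and without DMSO replicate 1, where the shift was 0.002. Without DMSO replicate 2 the shift was -0.302.

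Histone genes rose in 47 of 62 cases with OTX-015 (50 adjusted over the list alone), with a median shift of 1.23 (adjusted p = 9.46e-12, and 0.469 with an estimated correlation). Many of these genes are low, with a median of 1.23 RPKM in DMSO over the 70 listed. The filter can keep such members through the compound libraries where they are high, which favours rises. H1f0, a linker histone of resting cells, rose 5.28-fold from 62.1 ± 0.975 to 328 ± 23.6 RPKM, Hist1h1c rose 6.9-fold from 4.51 ± 0.292 to 31.1 ± 0.137 RPKM and Hist1h2bc rose 6.88-fold from 9.58 ± 0.306 to 65.9 ± 5.24 RPKM. The OTX-015 libraries differed in this list, whose shift was 0.614 without OTX-015 replicate 2 and 1.841 without OTX-015 replicate 1, and near-identical histone genes share reads. Genes known to be induced by BET inhibitors rose in 10 of 12 cases (11 adjusted over the list alone; adjusted p = 3.72e-07, and 0.171 with an estimated correlation). Zmynd8 of that list went the other way, from 25.5 and 30.6 RPKM in the DMSO libraries to 12.4 and 11.1 RPKM. Genes of the BET proteins and P-TEFb rose in 11 of 22 cases (11 adjusted over the list alone; adjusted p = 0.00603, and 0.593 with an estimated correlation). They included Ell2 (5.66 ± 0.339 to 18.7 ± 0.643 RPKM). Immediate early genes rose in 23 of 30 cases (23 adjusted over the list alone) with a median shift of 0.96 (adjusted p = 1.41e-07, and 0.469 with an estimated correlation). They included Ier5 (4.48 ± 0.536 to 17.1 ± 0.976 RPKM). Fosl1 fell from 16 ± 0.06 to 3.79 ± 0.332 RPKM. Autophagy and lysosome genes rose in 24 of 40 cases (24 adjusted over the list alone; adjusted p = 7.77e-06, and 0.569 with an estimated correlation). They included Ulk1 (4.9 ± 1.15 to 17 ± 1.53 RPKM) and Ctsl (15.1 ± 0.446 to 47.1 ± 1.21 RPKM).

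Cholesterol genes rose with OTX-015 in 18 of 25 cases (18 adjusted over the list alone) with a median shift of 0.54 (adjusted p = 3.41e-05, and 0.469 with an estimated correlation). They included Idi1 (126 ± 6.43 to 262 ± 16.2 RPKM) and Insig1 (33.6 ± 0.275 to 58.1 ± 4.39 RPKM). NRF2 targets rose in 11 of 23 cases (11 adjusted over the list alone; adjusted p = 0.019, and 0.652 with an estimated correlation). They included Hmox1 (13.1 ± 1.43 to 42.1 ± 1.51 RPKM) and Gclc (21.7 ± 1.14 to 58.6 ± 3.63 RPKM). Targets of p53 rose in 13 and fell in 9 of 26 cases (14 and 9 adjusted over the list alone; adjusted p = 0.0157, and 0.651 with an estimated correlation). That call was lost with no filter on low values (adjusted p = 0.0788) and after upper-quartile scaling (0.0505), over a range of 0.00287 to 0.0788. Among them the pro-death gene Bcl2l11 rose 4.23-fold from 4.62 ± 0.0877 to 19.5 ± 1.16 RPKM and Btg2 rose 3.59-fold from 3.08 ± 0.255 to 11 ± 0.89 RPKM.

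Other lists did not pass camera with OTX-015, although single members changed. Of interferon genes 5 rose and 13 fell of 26 (5 and 13 adjusted over the list alone; adjusted p = 0.312), and the list passed with no filter on low values (0.0398). Of NF-kB genes 9 rose and 9 fell of 20 (9 and 9 alone; adjusted p = 0.389), and among MLL and HOX targets 7 rose and 4 fell of 17 (7 and 5 alone; adjusted p = 0.102). Irf7 rose from 1.54 ± 0.235 to 8.07 ± 1.25 RPKM, Gbp3 fell from 10.3 ± 0.227 to 1.81 ± 0.126 RPKM, Ccl3 fell from 115 ± 11 to 24.1 ± 1.23 RPKM and Mllt3 rose from 24.8 ± 0.354 to 54.7 ± 3.93 RPKM. LXR and lipid genes rose in 6 and fell in 3 of 12 cases (6 and 3 adjusted over the list alone; adjusted p = 0.148), with a positive median and a mean log2 fold change of -0.03. Apoe fell from 6 ± 0.407 to 1.65 ± 0.132 RPKM. ATF4 targets rose in 10 and fell in 9 of 29 cases (11 and 9 adjusted over the list alone; adjusted p = 0.221). They included a rise of Sesn2 (5.36 ± 0.269 to 14.8 ± 1.18 RPKM) and a drop of Slc7a1 (27.9 ± 2.87 to 9.35 ± 0.971 RPKM). Genes of the unfolded protein response rose in 4 and fell in 7 of 21 cases (4 and 7 alone; adjusted p = 0.988). Heat shock genes rose in 5 and fell in 8 of 17 (5 and 8 alone; adjusted p = 0.988) and glycolysis genes rose in 3 and fell in 8 of 21 (3 and 8 alone; adjusted p = 0.79). Mitosis genes rose in 10 and fell in 13 of 47 cases (7 and 11 adjusted over the list alone; adjusted p = 0.389). Cytosolic ribosomal proteins fell in 17 of 75 cases (0 adjusted over the list alone; adjusted p = 0.114), although the list passed in 3 of 21 settings, over a range up to 0.823. These were without DMSO replicate 2 (shift -0.257, adjusted p = 0.00187), with the replicate number as a block (0.0206) and with no filter on low values (0.0479). Hspd1, a mitochondrial chaperone, fell from 387 ± 2.46 to 166 ± 8.77 RPKM.

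The comparison of BBC1115 with DMSO asked what the code-named compound did to the same transcripts. Myc fell 38.9-fold from 97.8 ± 2.72 to 2.51 ± 0.357 RPKM (log2 fold change -4.82, adjusted p = 4.29e-11). Hexim1 rose 8.13-fold from 23.3 ± 0.86 to 190 ± 9.11 RPKM (adjusted p = 4.11e-10), and Egr1 rose 24.8-fold from 12.4 ± 0.368 to 307 ± 5.49 RPKM. Myb fell 12.2-fold from 274 ± 1.72 to 22.4 ± 0.759 RPKM and Cdk6 fell 16.2-fold from 76.7 ± 14.4 to 4.72 ± 0.467 RPKM. Gfi1 fell 47.3-fold from 47.1 ± 0.524 to 0.996 ± 0.0259 RPKM and Lmo2 fell 10.8-fold from 350 ± 19.9 to 32.3 ± 1.89 RPKM. Hpgd, which encodes an enzyme that breaks down prostaglandins, fell 29.6-fold from 330 ± 21.3 to 11.2 ± 0.546 RPKM, and Tifab fell 32.6-fold from 69 ± 5.84 to 2.11 ± 0.23 RPKM. Brd2 rose 6.92-fold to 469 ± 10.2 RPKM, and Brd3 did not pass (12.8 ± 0.363 RPKM, adjusted p = 0.0645), although it passed without DMSO replicate 1 (0.014) and with length trends removed (0.0144), over a range up to 0.961. Insig1, which holds back cholesterol synthesis, rose 10.6-fold from 33.6 ± 0.275 to 357 ± 1.94 RPKM. Tob1 rose 24.2-fold to 115 ± 6.78 RPKM, Kctd12 15.8-fold to 229 ± 12.7 RPKM, Sertad1 12.7-fold to 120 ± 13.4 RPKM and Cdkn1a 3.78-fold to 251 ± 5.73 RPKM. Hoxa9 did not pass (82.6 ± 8.13 RPKM, adjusted p = 0.122) with the values as deposited. It passed as higher after quantile normalization (0.000452), after upper-quartile scaling (0.000865), as TPM (0.00636) and without BBC1115 replicate 2 (0.0474). Meis1 rose to 12.5 ± 0.206 RPKM (log2 fold change 0.23, adjusted p = 0.0408), a call lost without each of 6 libraries, both of DMSO, both of RVX-208 and both of BBC1115, where the adjusted p ran from 0.0749 to 0.15.

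In total 2629 genes rose and 4915 fell with BBC1115, of which 800 and 1962 changed by at least 1 on the log2 scale. The median log2 fold change of all genes was -0.249 with the RPKM as deposited and -0.018 after upper-quartile scaling, under which 3743 genes were higher and 3960 lower, and quantile normalization gave 3889 and 3844.

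Of the lists that fell with OTX-015, all but oxidative phosphorylation fell with BBC1115 too. MYC targets fell in 57 of 61 cases (57 adjusted over the list alone) with a median shift of -1.23 (adjusted p = 8.81e-10, and 0.544 with an estimated correlation). DNA replication genes fell in 37 of 49 cases (37 adjusted over the list alone; adjusted p = 0.00102, and 0.544 with an estimated correlation). Wdr12 fell 8.04-fold from 37.9 ± 1.76 to 4.72 ± 0.244 RPKM, Tk1 fell 7.91-fold from 67 ± 2.84 to 8.47 ± 0.169 RPKM and Mcm2 fell 3.05-fold from 89.8 ± 6 to 29.5 ± 1.11 RPKM. BET-sensitive oncogenes fell in 12 of 15 cases (12 adjusted over the list alone; adjusted p = 0.00132, and 0.544 with an estimated correlation). BET-repressed genes fell in 10 of 10 cases (10 adjusted over the list alone; adjusted p = 0.000461, and 0.544 with an estimated correlation). Monocyte genes fell in 20 of 29 cases (20 adjusted over the list alone; adjusted p = 0.0234, and 0.544 with an estimated correlation). Neutrophil genes fell in 17 of 20 cases (17 adjusted over the list alone; adjusted p = 0.00653, and 0.544 with an estimated correlation). Cd14 fell 25.3-fold from 18.2 ± 0.0952 to 0.718 ± 0.0313 RPKM and Cebpe fell 17.3-fold from 83.1 ± 1.81 to 4.81 ± 0.329 RPKM. Mast cell and basophil markers fell in 5 of 5 cases (5 adjusted over the list alone; adjusted p = 0.0361, and 0.544 with an estimated correlation). That call was lost with no filter on low values (0.0935, over a range from 0.0217). Stem and progenitor genes fell in 9 of 13 cases (9 adjusted over the list alone) and missed the threshold (adjusted p = 0.0937).

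Cholesterol genes rose with BBC1115 in 21 of 25 cases (21 adjusted over the list alone) with a median shift of 1.41 (adjusted p = 7.45e-10, and 0.544 with an estimated correlation). They included Idi1 (4.44-fold, 126 ± 6.43 to 557 ± 15.4 RPKM). ATF4 targets rose in 18 of 29 cases (18 adjusted over the list alone) with a median shift of 0.77 (adjusted p = 7.72e-05, and 0.544 with an estimated correlation). They included Chac1 (7.25-fold, 1.58 ± 0.365 to 11.4 ± 0.103 RPKM) and Sesn2 (5.03-fold, 5.36 ± 0.269 to 26.9 ± 1.39 RPKM). Ddit3, which encodes the stress factor CHOP, was listed at 0 in both DMSO and both RVX-208 libraries, at 28 and 24.9 RPKM in OTX-015 and at 86.5 and 75 RPKM in BBC1115. NRF2 targets rose in 12 of 23 cases (12 adjusted over the list alone; adjusted p = 0.000804, and 0.544 with an estimated correlation). They included Srxn1 (5.11-fold, 9.11 ± 0.251 to 46.5 ± 0.525 RPKM) and Hmox1 (5.79-fold, 13.1 ± 1.43 to 75.9 ± 6.46 RPKM). Genes of the unfolded protein response rose in 9 and fell in 4 of 21 cases (8 and 4 adjusted over the list alone; adjusted p = 0.018, and 0.553 with an estimated correlation). That call was lost under quantile normalization (0.0531, over a range from 0.00345). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 414 ± 0.754 to 875 ± 44.3 RPKM. Heat shock genes rose in 9 and fell in 7 of 17 cases (9 and 7 adjusted over the list alone) and missed the threshold as a list (adjusted p = 0.0944). Dnajb1 rose 5.32-fold from 15.1 ± 0.395 to 80.3 ± 3.13 RPKM.

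Further lists rose with BBC1115, and for these only the members that rose are counted. Histone genes rose in 36 of 62 cases (32 adjusted over the list alone; adjusted p = 3.63e-09, and 0.544 with an estimated correlation). They included H1f0 (7.3-fold, 62.1 ± 0.975 to 453 ± 27.7 RPKM). Immediate early genes rose in 22 of 30 cases (22 adjusted over the list alone; adjusted p = 6.83e-07, and 0.544 with an estimated correlation). They included Junb (7.54-fold, 32.2 ± 1.6 to 243 ± 21.7 RPKM). BET-induced genes rose in 10 of 12 cases (10 adjusted over the list alone; adjusted p = 2.14e-06, and 0.218 with an estimated correlation). Zmynd8 of that list went the other way, from 25.5 and 30.6 RPKM in the DMSO libraries to 3.59 and 4.19 RPKM. BET and P-TEFb genes rose in 11 of 22 cases (11 adjusted over the list alone; adjusted p = 0.0157, and 0.544 with an estimated correlation). Larp7 of that list stood lower, at 40.7 and 40.4 RPKM in DMSO and 16.71 and 18.85 RPKM with BBC1115. Hexim2 did too, at 2.25 and 2.08 RPKM against 0.51 and 0.32 RPKM. Autophagy genes rose in 26 of 40 cases (26 adjusted over the list alone; adjusted p = 4.91e-06, and 0.544 with an estimated correlation). They included Ulk1 (5.62-fold, 4.9 ± 1.15 to 27.5 ± 2.13 RPKM). Targets of p53 rose in 14 of 26 cases (14 adjusted over the list alone; adjusted p = 0.00243, and 0.544 with an estimated correlation). They included Btg2 (9.25-fold, to 28.4 ± 2.2 RPKM) and Gadd45b (8.27-fold, 7.68 ± 0.333 to 63.5 ± 4.34 RPKM). Ribosomal proteins shifted by 0.36 (adjusted p = 0.000914, and 0.741 with an estimated correlation), with 8 of 75 higher (2 adjusted over the list alone). That call was lost without DMSO replicate 2 (shift 0.222, adjusted p = 0.102) and under quantile normalization (0.741), over a range from 2.41e-07.

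The other lists missed the threshold with BBC1115. LXR genes rose in 6 and fell in 3 of 12 cases (8 and 3 adjusted over the list alone; adjusted p = 0.0732), and mitosis genes rose in 4 and fell in 26 of 47 (3 and 26 alone; 0.253). Interferon genes rose in 5 and fell in 16 of 26 cases (5 and 16 alone; 0.42) and NF-kB genes rose in 9 and fell in 10 of 20 (9 and 10 alone; 0.554). Glycolysis genes rose in 6 and fell in 9 of 21 cases (6 and 8 alone; 0.568), and MLL and HOX targets rose in 5 and fell in 6 of 17 (5 and 6 alone; 0.726). Oxidative phosphorylation genes rose in 2 and fell in 21 of 56 cases (1 and 19 alone; 0.677). In that last list the median shift was 0.09 and the test pointed down. Plk1, a mitotic kinase, fell from 56.9 ± 4.12 to 23.7 ± 0.912 RPKM and Irf7 rose 7.95-fold from 1.54 ± 0.235 to 12.2 ± 0.546 RPKM. Nfkbiz rose 9.4-fold from 1.54 ± 0.333 to 14.5 ± 0.694 RPKM and Hoxa7 fell from 14.6 ± 1.25 to 3.98 ± 0.475 RPKM.

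RVX-208 was compared with DMSO to set an inhibitor that favours the second bromodomain beside the others. Egr1 rose 2.63-fold from 12.4 ± 0.368 to 32.5 ± 0.5 RPKM (log2 fold change 1.33, adjusted p = 8.03e-06). Ccr2 fell 2.15-fold from 21.1 ± 0.173 to 9.8 ± 0.393 RPKM (adjusted p = 0.000952). Egr1 and Ccr2 passed in 21 of 21 settings. Myc fell 1.55-fold from 97.8 ± 2.72 to 63.2 ± 1.37 RPKM (log2 fold change -0.62, adjusted p = 0.0355). Hist1h1c rose from 4.51 ± 0.292 to 7.82 ± 0.151 RPKM, H1f0 from 62.1 ± 0.975 to 94.3 ± 0.748 RPKM, Trp53inp2 from 4.72 ± 0.102 to 8.12 ± 0.376 RPKM and Zfp809 from 8.01 ± 1.1 to 13.4 ± 0.82 RPKM. Gng11 fell from 7.28 ± 0.47 to 3.76 ± 0.13 RPKM, Gnl3 from 89.5 ± 3.72 to 61.2 ± 0.874 RPKM and Ydjc from 19 ± 1.53 to 10.2 ± 0.875 RPKM. Natd1, named after its values were seen because its mean lay under the minimum for naming, rose from 2.2 ± 0.097 to 4.01 ± 0.321 RPKM (adjusted p = 0.0413), and it was not run under the alternatives.

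Calls with RVX-208 were few, 9 genes higher and 8 lower at an adjusted p under 0.05, with 1820 genes at an unadjusted p under 0.05. The named genes other than Egr1 and Ccr2 passed in 9 (Ydjc) to 15 (H1f0, Hist1h1c and Trp53inp2) of 21 settings. Myc passed in 10 of 21 settings (adjusted p 0.0108 to 0.218) and missed without DMSO replicate 1 (0.0668), RVX-208 replicate 1 (0.167), RVX-208 replicate 2 (0.218), OTX-015 replicate 1 (0.12) or OTX-015 replicate 2 (0.121). Without either RVX-208 library or either OTX-015 library, Hist1h1c, H1f0, Trp53inp2, Zfp809, Gng11, Gnl3 and Ydjc missed too, with adjusted p from 0.065 to 0.252. Zfp809, Gng11 and Ydjc also missed without DMSO replicate 1 (0.0646 to 0.0884). Without DMSO replicate 2 the counts were 625 higher and 360 lower. Without RVX-208 replicate 2 they were 3 and 5, without RVX-208 replicate 1 the higher count was 4, without either OTX-015 library 3 and 3, and without DMSO replicate 1 the higher count was 17. Among the other calls, Nab2, Ddb2 and Raet1c (higher) and Cebpzos and Raet1e (lower) are listed at 0 in some libraries. Nab2, which encodes a partner of EGR1, was listed at 0 in both DMSO libraries and at 11.2 and 11.9 RPKM in RVX-208, 23.8 and 22.6 in OTX-015, and 30.9 and 27.9 in BBC1115.

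Hexim1 did not pass with RVX-208 (30.2 ± 0.776 RPKM against 23.3 ± 0.86, log2 fold change 0.36 with a 95% interval of 0.17 to 0.55, adjusted p = 0.123). It passed in 2 of 21 settings, as TPM (log2 fold change 0.46, adjusted p = 0.0212) and with length trends removed (0.40, 0.0405), over a range up to 0.538. The threshold was also missed by Brd2 (79.5 ± 0.223 RPKM, adjusted p = 0.227), Myb (246 ± 3.74 RPKM, 0.328), Cdk6 (83.7 ± 1.2 RPKM, 0.542), Meis1 (12.7 ± 0.855 RPKM, 0.222) and Kit (0.419). For Myb the interval of the log2 fold change ran from -0.33 to 0.02. MYC targets fell as a list with RVX-208, by a median of -0.28 relative to all genes (adjusted p = 2.23e-20, and 0.46 with an estimated correlation), with 1 of 61 lower over all genes and 37 lower when adjusted over the list alone. BET-induced genes shifted by 0.24 (adjusted p = 0.000105, and 0.407 with an estimated correlation; 1 of 12 higher, and 4 adjusted over the list alone). BET-repressed genes shifted by -0.27 (0.000132, and 0.46 with an estimated correlation; 2 of 10 lower, and 5 adjusted over the list alone). BET and P-TEFb genes shifted by 0.16 (0.00397, and 0.691 with an estimated correlation; 0 of 22 higher, and 4 adjusted over the list alone), and by 0.05 without DMSO replicate 1 and 0.273 without DMSO replicate 2. Monocyte genes shifted by -0.16 (1.16e-06, and 0.46 with an estimated correlation; 1 of 29 lower, and 7 adjusted over the list alone), and by -0.238 without DMSO replicate 2. Neutrophil genes shifted by -0.21 (6.95e-06, and 0.545 with an estimated correlation; 0 of 20 lower, and 3 adjusted over the list alone), and by -0.135 to -0.304 without single libraries. With length trends removed their shift was -0.101.

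Shifts with RVX-208 were spread over other lists too. Ribosomal proteins shifted by -0.22 (adjusted p = 2.09e-11, and 0.691 with an estimated correlation; 0 of 75 lower, and 0 adjusted over the list alone), and by -0.061 without DMSO replicate 1 and -0.362 without DMSO replicate 2. Quantile normalization, 1 of 21 settings, ended the call (shift -0.042, adjusted p = 0.051). With length trends removed the shift was -0.118, and that of the oxidative phosphorylation genes, given next, was -0.059. Oxidative phosphorylation genes shifted by -0.16 (1.51e-07, and 0.691 with an estimated correlation; 0 of 56 lower), and by -0.024 without DMSO replicate 1, where the call was lost (0.191, over a range from 6.27e-14), and -0.324 without DMSO replicate 2. Immediate early genes shifted by 0.11 (0.00324, and 0.691 with an estimated correlation; 1 of 30 higher, and 4 adjusted over the list alone), and missed without DMSO replicate 2 (0.0877, over a range from 9.15e-06). Cholesterol genes shifted by 0.12 (0.00344, and 0.691 with an estimated correlation; 0 of 25 higher, and 0 adjusted over the list alone), and missed without DMSO replicate 2 (0.104, over a range from 2.29e-05). Autophagy genes shifted by 0.06 (0.0401, and 0.791 with an estimated correlation; 0 of 40), with a call in 18 of 21 settings (0.000285 to 0.344). That call was lost without DMSO replicate 2 (0.344), RVX-208 replicate 1 (0.0628, with a shift of 0.024) or RVX-208 replicate 2 (0.0561). BET-sensitive oncogenes shifted by -0.10 (0.046, and 0.691 with an estimated correlation; 1 of 15 lower, and 3 adjusted over the list alone), with a call in 13 of 21 settings (0.00112 to 0.518). They missed without DMSO replicate 2 (0.518), RVX-208 replicate 2 (0.179) or either BBC1115 library (0.054). Glycolysis genes shifted by -0.09 (0.0251, and 0.691 with an estimated correlation; 0 of 21 lower, and 1 adjusted over the list alone), with a call in 17 of 21 settings (0.00528 to 0.309). They missed without DMSO replicate 2 (0.139), RVX-208 replicate 1 (0.0517) or RVX-208 replicate 2 (0.0561). The other lists did not pass, with adjusted p from 0.0548 for mast cell and basophil markers to 0.783 for DNA replication. Some of them passed without a single library. Histone genes (0.111, and 5.42e-05 with length trends removed) shifted by 0.023 to 0.151 over libraries left out. Mast cell markers passed without DMSO replicate 1 (0.0267, with a shift of -0.327), RVX-208 replicate 2 (0.0242), OTX-015 replicate 1 (0.0496) or OTX-015 replicate 2 (0.0498), over a range from 0.0181 to 0.139. Mitosis genes passed without DMSO replicate 1 (0.0479) or either OTX-015 library (0.0496 and 0.0498), over a range from 0.000741 to 0.175. Heat shock genes passed without DMSO replicate 1 (0.0413, over a range from 0.0373 to 0.482). Under quantile normalization mitosis genes (0.000741), MLL and HOX targets (0.0219) and NRF2 targets (0.0176) passed as higher. So did MLL and HOX targets as TPM (0.0371) and NF-kB genes with length trends removed (0.0275). Mitosis genes also passed with no filter (0.022), after upper-quartile scaling (0.0267), as TPM (0.0146) and with length trends removed (0.0478).

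**Figure D2:**
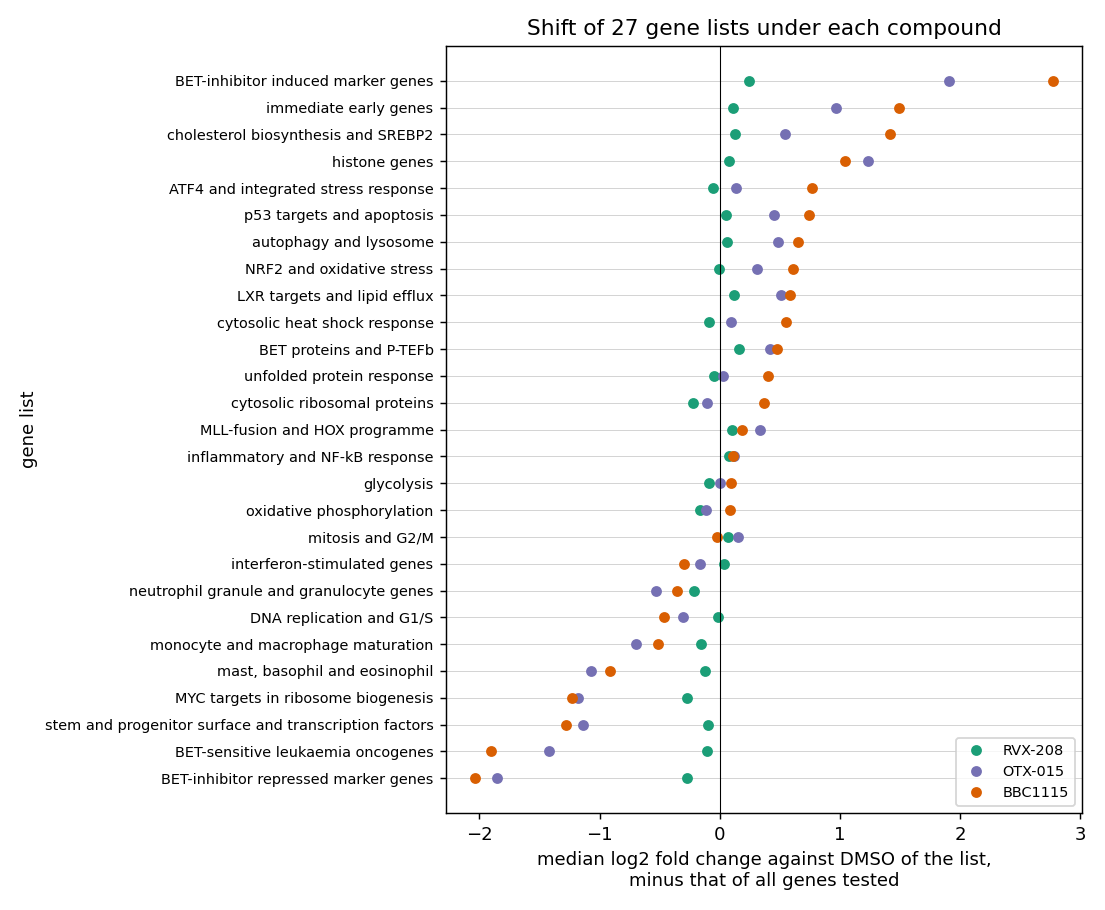
Median log2 fold change against DMSO of each of the 27 gene lists, less the median of all genes, with a point for each compound. MYC targets of ribosome biogenesis lie at -1.18 with OTX-015, -1.23 with BBC1115 and -0.28 with RVX-208, and the cholesterol list at 0.54, 1.41 and 0.12.

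BBC1115 was then compared directly with OTX-015, to ask whether the code-named compound and the known inhibitor left different transcripts. Insig1 was 6.15-fold higher with BBC1115 (357 ± 1.94 against 58.1 ± 4.39 RPKM, adjusted p = 9.53e-09) and Chac1 4.41-fold higher (11.4 ± 0.103 against 2.59 ± 0.304 RPKM). Cth was 3.64-fold higher (13.6 ± 2.17 against 3.73 ± 0.152 RPKM) and the metallothionein gene Mt2 3.13-fold higher (60 ± 2.84 against 19.1 ± 0.793 RPKM). Hpgd was 6.22-fold lower (11.2 ± 0.546 against 69.5 ± 7.33 RPKM) and Myb 4.13-fold lower (22.4 ± 0.759 against 92.7 ± 5.59 RPKM). Cebpe was 4.4-fold lower (4.81 ± 0.329 against 21.2 ± 3.73 RPKM), Fmnl1 4.1-fold lower (6.78 ± 0.0528 against 27.8 ± 3.36 RPKM) and Cdk6 3.99-fold lower. Hexim1 was 1.56-fold higher (adjusted p = 0.000195), Brd2 2.1-fold higher and Egr1 1.8-fold higher. Myc was 1.49-fold lower (log2 fold change -0.44, adjusted p = 0.00351), but not after quantile normalization, where the log2 difference was -0.21 (adjusted p = 0.0769). Ccr2 did not differ past the threshold (log2 difference -0.11, 95% interval -0.33 to 0.11, adjusted p = 0.393), nor did Kit (-0.11, -0.33 to 0.11, 0.398) or Mpo (-0.08, -0.28 to 0.12, 0.492). The same held for Hoxa9 (-0.20, -0.40 to 0.01, 0.116) and Brd3 (-0.19, -0.43 to 0.05, 0.17). Some of these calls depend on the scaling. Hoxa9 was called lower with BBC1115 under quantile normalization (-0.29, adjusted p = 0.00391) and as TPM (-0.35, 0.000919). So was Mpo under quantile normalization (-0.26, 0.0159) and as TPM (-0.24, 0.0103), and Brd3 as TPM (-0.35, 0.0387). These intervals do not show that the compounds act alike on these genes.

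Between BBC1115 and OTX-015, 1413 genes were higher and 2964 lower with BBC1115, of which 92 and 261 differed by at least 1 on the log2 scale. The higher count moved with the scaling, to 890 as TPM, 2124 after upper-quartile scaling and 2269 after quantile normalization, beside 4310, 2740 and 2339 lower. Without OTX-015 replicate 2 the higher count was 796, without BBC1115 replicate 1 it was 861, and without OTX-015 replicate 1 the lower count was 1867.

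Cholesterol genes were higher with BBC1115 than with OTX-015 in 20 of 25 cases (20 adjusted over the list alone), with a median shift of 0.87 (adjusted p = 3.25e-17, and 0.518 with an estimated correlation). They included Sc5d (142 ± 3.91 against 56 ± 1.88 RPKM) and Msmo1 (180 ± 18 against 71.1 ± 3.76 RPKM). ATF4 targets were higher in 21 of 29 cases (23 adjusted over the list alone) with a median shift of 0.59 (adjusted p = 1.48e-13, and 0.518 with an estimated correlation). They included Atf3 (7.19 ± 0.622 against 1.94 ± 0.3 RPKM). NRF2 targets were higher in 13 of 23 cases (14 adjusted over the list alone; adjusted p = 2.75e-05, and 0.625 with an estimated correlation). They included Srxn1 (46.5 ± 0.525 against 15 ± 0.568 RPKM). Heat shock genes were higher in 11 of 17 cases (13 adjusted over the list alone; adjusted p = 1.88e-06, and 0.518 with an estimated correlation). They included Dnajb1 (80.3 ± 3.13 against 29.6 ± 1.75 RPKM). Genes of the unfolded protein response were higher in 11 of 21 cases (13 adjusted over the list alone; adjusted p = 2.75e-05, and 0.518 with an estimated correlation). They included Dnajb9 (22.7 ± 3.62 against 9.83 ± 1.34 RPKM). Immediate early genes were higher in 17 of 30 cases (18 adjusted over the list alone; adjusted p = 6.7e-06, and 0.518 with an estimated correlation). They included Junb (243 ± 21.7 against 82.2 ± 8.33 RPKM). Targets of p53 were higher in 14 of 26 cases (15 adjusted over the list alone; adjusted p = 0.000397, and 0.625 with an estimated correlation). Ribosomal proteins were higher in 46 of 75 cases (70 adjusted over the list alone; adjusted p = 5.43e-15, and 0.625 with an estimated correlation). That call was lost under quantile normalization (0.124, over a range from 8.43e-30). BET-induced genes were higher in 6 of 12 cases (6 adjusted over the list alone; adjusted p = 0.00428, and 0.518 with an estimated correlation). This call too was lost under quantile normalization (0.0522, over a range from 3e-04).

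BET-sensitive oncogenes were lower with BBC1115 than with OTX-015 in 12 of 15 cases (12 adjusted over the list alone) with a median shift of -0.97 (adjusted p = 2.75e-05, and 0.518 with an estimated correlation). They included Gfi1 (6.21-fold) and Lmo2 (32.3 ± 1.89 against 91.1 ± 4.85 RPKM). MLL and HOX targets were lower in 10 of 17 cases (10 adjusted over the list alone; adjusted p = 0.00397, and 0.518 with an estimated correlation). They included Mef2c (17.8 ± 1.71 against 39 ± 2.27 RPKM). Mitosis genes were lower in 25 of 47 cases (26 adjusted over the list alone; adjusted p = 0.00121, and 0.625 with an estimated correlation). They included Bub1b (14.6 ± 1.26 RPKM with BBC1115, 2.11-fold lower). DNA replication genes were lower in 24 of 49 cases (24 adjusted over the list alone; adjusted p = 0.0227, and 0.729 with an estimated correlation). They included Tk1 (2.88-fold). Autophagy genes (adjusted p = 0.00571, and 0.729 with an estimated correlation; 9 higher and 5 lower of 40, and 9 and 4 adjusted over the list alone) were called higher but not under quantile normalization (0.139) or as TPM (0.062), over a range from 0.00202. Oxidative phosphorylation genes (0.00852, and 0.789 with an estimated correlation; 3 higher and 3 lower of 56, and 1 and 2 alone) held in 16 of 21 settings (4.26e-05 to 0.381), with a shift that changed sign under quantile normalization (-0.034), and missed without BBC1115 replicate 1 (0.305). Histone genes did not pass (0.12), with a shift that ran from -0.431 without OTX-015 replicate 1 to 0.438 without OTX-015 replicate 2. With all libraries the test pointed up while the median shift was -0.09. They were called higher with a filter of 5 RPKM (shift 0.348, adjusted p = 0.00295) and as TPM (0.00337), where the median shift was -0.099 and the test again pointed up. The other lists missed the threshold, with adjusted p of 0.0679 for stem and progenitor genes (0.0355 to 0.526 over the settings, passing in 3 of 21), 0.0934 for MYC targets (0.0476 after upper-quartile scaling), 0.0967 for LXR (0.0487 without BBC1115 replicate 1 and 0.0496 with a filter of 5 RPKM, over a range up to 0.216), and 0.104 for glycolysis. It was 0.202 for BET and P-TEFb, 0.242 for BET-repressed genes, 0.593 for NF-kB, 0.8 for interferon, and 0.927 for monocyte, neutrophil and mast cell genes.

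**Figure D3:**
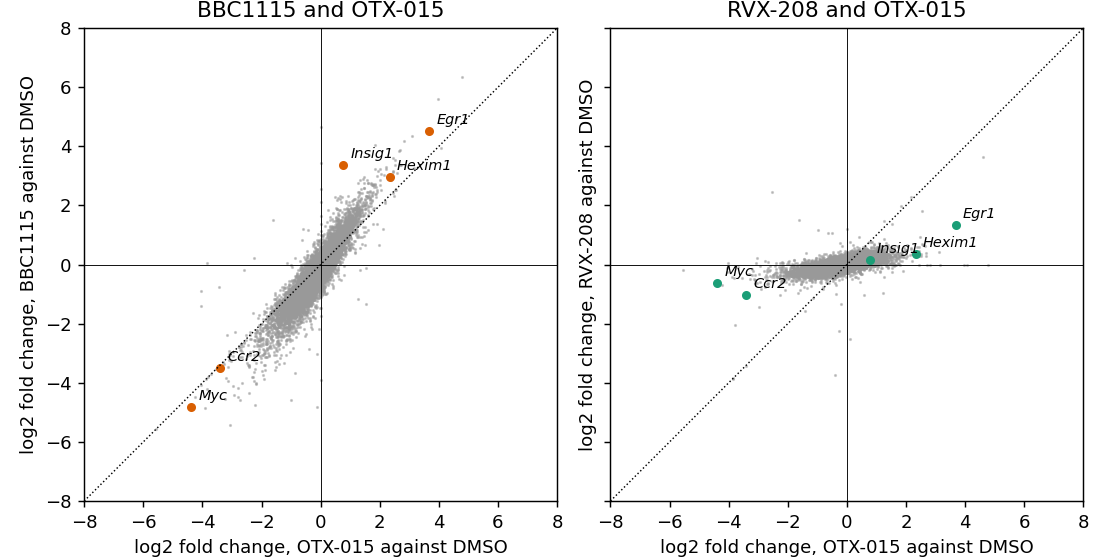
Log2 fold changes against DMSO of BBC1115 and of RVX-208 plotted over those of OTX-015, a point for each gene, with 5 genes marked and a dotted line where the compounds are equal. Insig1 lies at 3.37 with BBC1115 and 0.77 with OTX-015, and Myc at -4.82, -0.62 and -4.38 with BBC1115, RVX-208 and OTX-015.

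RVX-208 was also compared directly with the other compounds. Myc was 16.9-fold higher with RVX-208 than with OTX-015 (log2 difference 3.76, adjusted p = 1.25e-09) and 25.2-fold lower with BBC1115 than with RVX-208 (-4.20, adjusted p = 1.3e-10). Hexim1 was 4.03-fold lower with RVX-208 than with OTX-015 (-1.97, adjusted p = 3.23e-08), and 6.27-fold higher with BBC1115 than with RVX-208. Tob1 (6.7 ± 0.752 RPKM with RVX-208) was 7.24-fold lower than with OTX-015, Kctd12 (17.8 ± 0.92 RPKM) 5.51-fold lower and Cldn15 (27.7 ± 0.295 RPKM) 19.1-fold higher. Hpgd (280 ± 9.18 RPKM with RVX-208) was 25-fold lower with BBC1115, Pecam1 (59.6 ± 1.02 RPKM) 28.9-fold lower and Sla (30.7 ± 0.991 RPKM) 54.8-fold lower. RVX-208 had 3803 genes higher and 1752 lower than OTX-015, and BBC1115 had 2382 higher and 4950 lower than RVX-208. After upper-quartile scaling these were 2964 and 2808, and 3414 and 4037. Of the gene lists, 7 were higher and 8 lower with RVX-208 than with OTX-015, and 12 were higher and 4 lower with BBC1115 than with RVX-208, and none of these passed with an estimated correlation.

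The responses were then compared gene by gene. OTX-015 and BBC1115 shared 2066 genes that rose (637.3 if independent) and 3709 that fell (1967 if independent), and 35 moved in opposite directions. Their log2 fold changes correlated across genes at r = 0.909, against a mean of 0.494 in 100 simulated sets that had only the DMSO libraries in common. The r of OTX-015 with RVX-208 was 0.618 (0.501 simulated), and that of BBC1115 with RVX-208 was 0.443 (0.494 simulated). Because shared controls alone give an r of that size, covariances were compared. They were 0.628 (0.00848 simulated) for OTX-015 with BBC1115, 0.0973 (0.00862) for OTX-015 with RVX-208, and 0.0974 (0.00846) for BBC1115 with RVX-208. There were 2 DMSO libraries, so the controls could not be split between the compounds. RVX-208 shared 8 higher genes with OTX-015 (2.2 if independent) and 8 with BBC1115 (2.4), and 7 lower genes with each (3.2 and 3.9), and 1 gene moved in opposite directions in either pair. Simulated sets of unchanged groups with shared DMSO libraries held a mean of 0.22, 0.26 and 0.18 shared genes for the 3 pairs. Independence leaves out the shared controls and that simulation leaves out the effects. In 100 simulated sets that kept both, with RVX-208 unchanged, RVX-208 shared a mean of 0.5 genes with OTX-015 (0 to 5 over the sets) and 0.5 with BBC1115 (0 to 6), higher and lower together. For OTX-015 with BBC1115 no such sets were made, and part of the excess may come from the shared controls. Over 6312 genes that passed with OTX-015, the slope of the BBC1115 response on that of OTX-015 was 1.321 and that of RVX-208 was 0.179 (0.0142 in the sets with RVX-208 unchanged). Of the 2377 genes that rose with OTX-015 and hold no value of 0, 89.9% had a positive log2 fold change with RVX-208 (54.8% in those simulated sets), with a median of 0.17 (0.0132 simulated), beside 0.55 for OTX-015 and 0.72 for BBC1115. Of the 3935 that fell, 76.9% were negative with RVX-208 (53.6% simulated), with a median of -0.11 (-0.0096 simulated), beside -0.64 and -0.96. With no effect of any compound, 66.6% of all genes had the same sign with OTX-015 and RVX-208. The simulated genes vary independently, which real genes do not.

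Of the lists fixed for other cells, mast cell and basophil markers had the minimum of 5 kept genes and are given above. Of the rest, 1 gene was kept for T and NK cells, 1 for B cells, 2 for erythroid cells and megakaryocytes, and 3 for fibroblasts and stroma. Of the targets of the aryl hydrocarbon receptor 3 were kept. These 5 lists lie under the minimum of 5. Some of the kept genes were abundant, such as Vim, a fibroblast gene at 356 RPKM in DMSO and between 282 and 432 RPKM with the compounds, and Tfrc, an erythroid gene at 111 RPKM in DMSO and 74.6 to 97.4 RPKM with the compounds, both named after their values were seen. Nkg7, an NK marker, averaged 3.63 RPKM in DMSO, 1.66 with RVX-208, 1.59 with OTX-015 and 1.46 with BBC1115. The B cell gene Vpreb1 stayed at or below 1.09 RPKM in every group mean. Pecam1, an endothelial and myeloid adhesion gene, averaged 54.2 RPKM in DMSO, 59.6 with RVX-208, 6.98 with OTX-015 and 2.06 with BBC1115.

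Some genes are listed at exactly 0 in libraries beside high values in others. Of the kept genes 151 hold a 0, and 67 of these reach 5 RPKM elsewhere. Tnfrsf12a, a receptor for the cytokine TWEAK, was listed at 0 in both DMSO and both RVX-208 libraries, at 14.8 and 14.4 RPKM in OTX-015 and at 51.7 and 44.8 RPKM in BBC1115. Bysl, a ribosome assembly gene, stood at 16.4 and 15 RPKM in DMSO and 13.1 and 12.8 RPKM in RVX-208 and was listed at 0 with the other compounds. Mettl3, an RNA methyltransferase gene, stood between 13.3 and 15.4 RPKM in the other libraries and was listed at 0 in both BBC1115 libraries. In some genes replicates disagreed: Slirp was listed at 0 and 90.7 RPKM in the RVX-208 libraries and at 0 and 92.1 RPKM in the OTX-015 libraries, and Usp16 at 0 and 19 RPKM in DMSO. No fold is given for any of these genes.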

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

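The tests without genes listed at 0 and with length trends removed were chosen after seeing the data. So were the spread used to judge r and slopes, and the choice to give lists one by one for 4 of the 6 contrasts. A planned fit on whole reads was not run, because RPKM of genes with several isoforms could not be turned into reads. Leaving out a library leaves its group with 1, whose spread is assumed to be that of the other groups. Of 662 results for named genes, between 632 and 662 kept direction and side of the threshold under each setting that scores all of them, and under quantile normalization 636 did. Of 108 results for lists 87 did so under quantile normalization, 97 under upper-quartile scaling and 96 as TPM. With an estimated correlation 62 lost their call and 0 lists passed in any contrast. The cause was not tested for the changes that follow, except that a threshold of 1 on the log2 scale removes genes by construction, and fry tests a direction without comparing a list with other genes. Depth, estimated at 10700000 reads and above, limits calls on low genes.

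With RVX-208 against DMSO the 9 higher genes became 3 with no filter, 4 with only the 2 groups compared, 20 with robust variance, 4 at a log2 change of 1, 21 at an adjusted p under 0.1 and 34 with length trends removed. The 8 lower genes became 4 with a pseudocount of 0.1, 4 with no filter, 3 after upper-quartile scaling, 4 as TPM, 3 with only the 2 groups compared and 28 with robust variance. They became 4 at a log2 change of 1, 25 at an adjusted p under 0.1, 13 without genes listed at 0 and 23 with length trends removed. Leaving out single libraries gave 3 (without RVX-208 replicate 2) to 625 (without DMSO replicate 2) higher and 3 (without OTX-015 replicate 1) to 360 (without DMSO replicate 2) lower. The 5 higher lists became 8 under quantile normalization, 8 with length trends removed, 1 by fry, and 2 (without DMSO replicate 2) to 7 over libraries left out. The 8 lower lists became 5 under quantile normalization and 1 by fry.

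With the replicate number as a block RVX-208 had 20 lower genes, and the ribosomal proteins of OTX-015, which missed the threshold without it, were called lower (-0.106, adjusted p = 0.0206). The deviations of replicates from their group correlated at 0.52 between DMSO and BBC1115 and between -0.08 and 0.06 for the other pairs. Under the block the unfolded protein list of OTX-015 stood at 0.024 and the heat shock list at 0.092, each with the test in the other direction and neither past the threshold.

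Under quantile normalization 3641 genes were higher with OTX-015 than with DMSO, 2269 with BBC1115 than with OTX-015 and 3745 with BBC1115 than with RVX-208, and 3171 were lower with RVX-208 than with OTX-015. Upper-quartile scaling gave 2124 higher with BBC1115 than with OTX-015 and 2808 lower with RVX-208 than with OTX-015, and TPM gave 890 higher with BBC1115 than with OTX-015. At a log2 change of 1 the higher and lower counts were 368 and 970 for OTX-015, 800 and 1962 for BBC1115, 92 and 261 for BBC1115 against OTX-015, 648 and 1786 for BBC1115 against RVX-208, and 656 and 206 for RVX-208 against OTX-015. Between BBC1115 and OTX-015, leaving out libraries gave 796 (without OTX-015 replicate 2) to 1639 higher, with 861 without BBC1115 replicate 1, and 1867 (without OTX-015 replicate 1) to 3228 lower. Lists higher in that contrast became 7 under quantile normalization. By fry lists lower became 12 for BBC1115 against DMSO, 8 for BBC1115 against OTX-015 and 12 for BBC1115 against RVX-208, where no filter gave 7 and quantile normalization 7.

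The r of OTX-015 with BBC1115 was 0.895 with a pseudocount of 0.1, 0.921 without genes listed at 0 and 0.893 to 0.914 over libraries left out. That of OTX-015 with RVX-208 was 0.539, 0.681 and 0.563 to 0.638, and 0.58 as TPM. That of BBC1115 with RVX-208 was 0.399, 0.495 and 0.4 to 0.48. The slope of BBC1115 over genes called with OTX-015 was 1.273 under quantile normalization and 1.266 to 1.345 over libraries left out, and that of RVX-208 was 0.162 to 0.233. Over genes called with BBC1115 the slope of OTX-015 was 0.648, and 0.67 under quantile normalization and 0.613 as TPM. That of RVX-208 was 0.096 under quantile normalization, 0.094 after upper-quartile scaling, 0.067 as TPM, 0.083 with length trends removed and 0.082 to 0.113 over libraries left out.

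Values in the direction opposite to the reported one passed for MLL and HOX targets, NF-kB genes, Meis1 and histone genes in the settings stated, and missed the threshold for the other results that follow. For a list the value is its shift and the direction is that of the test, so a shift can keep its sign. Because fry tests a list against no change, its direction and p belong to the list's own fold changes and not to the shift relative to all genes, which is that of the main fit. With OTX-015, fry pointed the other way where the shift was 0.151 for mitosis, 0.116 for NF-kB, 0.51 for LXR, 0.024 for unfolded protein and 0.092 for heat shock genes. Unfolded protein genes stood at 0.033 and 0.028 with pseudocounts of 0.1 and 0.5, at -0.111 with no filter and at -0.023 to 0.05 over libraries left out. Heat shock genes stood at 0.111 after upper-quartile scaling, 0.11 as TPM and 0.042 to 0.128 over libraries left out, and glycolysis genes at 0.019, 0.018 and, with only the 2 groups compared, 0. Ribosomal proteins ran from -0.257 (without DMSO replicate 2, where they were called) to 0.027 (without DMSO replicate 1) over libraries left out. Brd3 stood at 0.072 under quantile normalization, 0.132 after upper-quartile scaling, 0.14 as TPM and -0.166 to 0.075 over libraries left out.

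With RVX-208, DNA replication genes stood at 0.023 under quantile normalization, -0.014 after upper-quartile scaling, -0.014 as TPM, -0.017 by fry and -0.018 to 0 over libraries left out. Stem cell genes stood at -0.09 with a filter of 5 RPKM, -0.1 by fry and -0.118 to -0.085 over libraries left out. Under quantile normalization interferon genes stood at -0.003, unfolded protein genes at 0.036, Bcl2 at -0.036, Hoxa9 at 0.028, Mpo at 0.1 and Serpini1 at -0.001. As TPM Csf1r stood at 0.018, Hoxa9 at 0.039 and Mpo at 0.047. With length trends removed Bcl2 stood at -0.093, Cdk6 at -0.03 and Serpini1 at -0.027. Over libraries left out LXR genes ran from 0.022 to 0.126, NRF2 from -0.033 to 0.012, Bcl2 from -0.098 to 0.123, Cdk6 from -0.053 to 0.328, Csf1r from -0.144 to 0.007, Hoxa9 from -0.134 to 0.022, Itgam from -0.028 to 0.216 and Serpini1 from -0.014 to 0.103.

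With BBC1115 against DMSO, fry called MLL and HOX targets lower (adjusted p = 0.00112, own median -0.065) and NF-kB genes lower (0.0035, own median -0.136), while their shifts relative to all genes were 0.183 and 0.113. The latter ran from 0.024 (without BBC1115 replicate 2) to 0.204 (without BBC1115 replicate 1) over libraries left out. For glycolysis, which missed with fry pointing down, the shift was 0.091. Oxidative phosphorylation genes stood at 0.114 after upper-quartile scaling and -0.081 to 0.251 over libraries left out, and Brd3 at 0.023 under quantile normalization and 0.005 after upper-quartile scaling. Against RVX-208, Meis1 was called higher under quantile normalization (0.283, adjusted p = 0.00651) and upper-quartile scaling (0.196, 0.0345), and stood at 0.008 with length trends removed and -0.079 to 0.049 over libraries left out.

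With BBC1115 against OTX-015, monocyte genes stood at 0.033 with a pseudocount of 0.1, -0.005 with a filter of 5 RPKM, -0.02 under quantile normalization, 0.102 as TPM, 0.055 with only the 2 groups compared, 0.055 by fry, 0.05 with length trends removed and 0.009 to 0.124 over libraries left out. Neutrophil genes stood at 0.007 with no filter, -0.119 under quantile normalization, 0.119 as TPM, 0.087 with only the 2 groups compared, 0.087 by fry, 0.036 with length trends removed and 0.077 to 0.141 over libraries left out. Mast, basophil and eosinophil genes stood at 0.096 by fry, 0.065 with length trends removed and 0.015 to 0.169 over libraries left out. Histone genes ran from -0.431 without OTX-015 replicate 1 to 0.438 without OTX-015 replicate 2, and both were called. Under quantile normalization interferon genes stood at 0.026, glycolysis at -0.007, oxidative phosphorylation at -0.034, Ccr2 at 0.045 and Kit at 0.087. Mpo ran from -0.18 to 0.015 over libraries left out.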

Other observations

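Among the tests in this part, those of symbol families, of the spread of list excesses, of genes at 0 split by whether replicates disagree, and of short-transcript lists with RVX-208 were chosen after the results were seen.

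Families of genes that share a symbol prefix, 161 in all, were tested outside the fixed lists. Genes of the mitochondrial ribosome fell with OTX-015, with 42 of 48 Mrpl genes lower (median log2 fold change -0.60, and -0.42 after upper-quartile scaling, adjusted p = 0.00041) and 25 of 29 Mrps genes lower (adjusted p = 0.00798). Subunits of the RNA exosome (10 of 10 Exosc genes, median -1.15), ribosomal RNA processing genes (8 of 8 Rrp genes, -1.37) and mitochondrial import genes (11 of 13 Timm genes, adjusted p = 0.0084) fell too, and 10 of 17 Kdm histone demethylase genes rose (adjusted p = 0.0129). With BBC1115, 40 of 48 Mrpl genes fell (adjusted p = 0.0239), as did 34 of 42 genes with a Cd symbol (-1.34, adjusted p = 0.00951) and 18 of 20 Mettl methyltransferase genes (adjusted p = 0.0221). Between BBC1115 and OTX-015, Hspa chaperone genes were higher with BBC1115 in 5 of 11 cases, and Arhgef genes were lower in 9 of 12 (adjusted p = 0.0316 for each). With an estimated correlation these families had adjusted p from 0.986 to 0.998.

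A larger response of the same kind as that to OTX-015 was tested as the source of the sterol and stress genes of BBC1115. Over 5717 genes called with both compounds, BBC1115 responses were 1.349 times those of OTX-015, and that multiple was subtracted. Cholesterol genes kept a median excess of 0.693 on the log2 scale (95% interval 0.443 to 0.957, members resampled), with Insig1 at 2.33, where the central 95% of 10000 random lists ran from -0.137 to 0.153. ATF4 targets kept 0.539 (0.389 to 0.673, random -0.154 to 0.126), with Chac1 at 1.62 and Cth at 1.53. Both lists thus lie above the bound set in advance for a single multiple of the OTX-015 response, which argues against that multiple. Random lists lack the correlation of real ones, and resampling treats members as independent. The spread between libraries enters neither interval, so the multiple is not excluded. NRF2 targets kept 0.267 (0.193 to 0.385, random -0.062 to 0.251), with Srxn1 at 1.34, which passes the bound set in advance by less than its spread, so a larger response of the same kind and a further one cannot be told apart for that list. A dose with a non-linear response was not tested, nor was any biological explanation of the excess.

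Genes listed at 0 in some libraries and at 5 RPKM or more in others numbered 67. Of those with an annotation 86.2% share exon with another protein-coding gene, against 22.7% of other genes (odds ratio 21.2, 95% interval 10.4 to 48.9, Fisher's exact test), which is what assignment of shared reads to a neighbour would give. In 22 of them the replicates of a group disagree, with 0 in one and at least 5 RPKM in the other (7 in DMSO, 9 in RVX-208, 8 in OTX-015 and 4 in BBC1115), which argues against real absence for those. Where both replicates of a group are at 0, in 51 genes such as Nab2 and Bysl, the odds ratio over the 49 with an annotation was 38.1 (13.9 to 146), and real absence and assignment of reads cannot be told apart without the reads. Values of 0 in the table may therefore reflect counting rather than expression in part of these genes.

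More genes fell than rose with BBC1115, with a median log2 fold change of -0.249. The 20 most abundant genes are excluded as the whole cause, since the median stayed at -0.165 without them in the totals. Medians of 4 groups of annotated exon length ran from -0.324 (shortest) to -0.122 (longest), which argues against that length as the whole cause. A single scaling factor for each library stays open. Upper-quartile scaling gave a median of -0.018, but it centres the values by construction and decides nothing, and TPM, which also applies 1 factor to each library, left -0.23 with 2763 genes higher and 4747 lower. RPKM cannot show a change in total RNA per cell, so a global drop in transcription and a difference in scaling cannot be told apart.

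Small list shifts with RVX-208 could come from transcript length, since the RVX-208 response changed by 0.087 on the log2 scale for each doubling of exon length and the DMSO replicates differed by 0.124. After removal of that trend, 13 of 13 lists were still called and their shifts were a median of 0.838 of the size before. Annotated exon lengths may differ from those of the transcripts expressed, so length is not excluded as the whole cause. For the 3 called lists with short transcripts the ratio was 0.473, so length may account for part of those shifts. Ribosomal proteins went from -0.221 to -0.118, oxidative phosphorylation from -0.164 to -0.059 and neutrophil genes from -0.214 to -0.101. No biological explanation of these small shifts was tested.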
